A study of Mus musculus with 8 samples.

How the data were processed

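H3K27ac chromatin immunoprecipitation libraries of the 266-6 line were analysed, 2 for each of 4 groups. Per the labels, siRNA against Arid1a or a non-targeting siRNA was used at 25 nM for 48 h, cells were starved of serum overnight, and EGF at 40 ng/ml or a vehicle of 0.1% BSA was given for 8 h. The level of Arid1a itself was not analysed here.

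The authors deposited 1 peak list per library, so peaks were called per sample and not on pooled samples. Each list has 9 columns and no header. Per the submitters' processing notes, Bowtie2 2.3.4.2, SAMtools, MACS2 2.1.1.20160309.0 and deepTools 3.0.2 were used with build mm9, without a stated role or order, and peak names in the deposited lists carry the name of MACS2. Whether an input library served as background, and the settings of the caller, are not given in the sources used here. The deposited score is the whole-number part of 10 times the −log10 q-value. The deposited fold enrichment is a ratio over the caller's background, and the deposited −log10 p and −log10 q of each peak come from the same caller. No deposited peak had a −log10 q under 1.00, was under 200 bp wide, or lay under 801 bp from the next peak of its list. Scores and fold enrichments are the authors' values and were used to rank peaks within a list. One setting kept peaks above the median score pooled over all lists, which compares scores between libraries, and these can differ with depth. Read depth is unknown, and deeper libraries can yield longer lists and wider peaks, so counts of peaks and covered length may differ between libraries for that reason.

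Peaks of all lists that overlapped by at least 1 bp were merged to 33920 regions. A region was called gained where both libraries of the first group had a peak in it and neither of the second did, and lost in the reverse case. Over both states of the other factor all 4 libraries against none were required. Pairwise counts were set beside the other splits of the same 4 libraries, since 2 against 2 cannot give a two-sided p under 0.333. Totals were compared by exact two-sided permutation of all 70 assignments. Similarity was measured by the base-pair Jaccard index, and tested against all ways to pair the 8 libraries and all 35 splits of them, one-sided. Covered length per region was tested with limma 3.58.1 (empirical Bayes with a trend) in R 4.3.3 on log2(covered bp + 200), with a mean for each of the 4 groups and the spread shared by all 8 libraries, over the 28146 regions with a peak in at least 2 libraries. P-values were adjusted by Benjamini-Hochberg over regions and the threshold was 0.05. Fold differences on this scale are understated for short peaks, and a region without a peak has a covered length of 0, which does not mean absence of acetylation. Median log2 differences over all regions were -0.14 and -0.32 for EGF in Arid1a-intact and knockdown cells, and 0.18 and 0 for knockdown without and with EGF. Width and chromosome of changed regions were compared with those of shared regions by Fisher's exact test. For width no p is given, since a region that lacks a peak in some libraries tends to be narrow whatever the groups. Other steps used Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.

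The interval steps were tested on made-up peaks and recovered all of 200 planted regions. Limma was tested on simulated data of 28146 regions with 100 regions changed by log2 1 and 100 by log2 2. With normal spread it found 8% and 31% of them for EGF in Arid1a-intact cells, with 1 false call, and 28% and 50% for the mean EGF effect, with 2 false calls. With residuals of the data reshuffled it found 15% and 42%, and 35% and 63%, with 47 and 61 false calls. Under reshuffling, unchanged regions reached the data's p limit at numbers equal to 17.3% of the calls for EGF in Arid1a-intact cells, 12.4% in knockdown cells, 10.4% for the mean EGF effect, 32.5% for knockdown without EGF, 43.0% with EGF and 54.5% for the mean knockdown effect, so the nominal false discovery rate of 0.05 was not held there.

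Groups, main tests, most alternatives and the rule for named regions were fixed before the data were examined. The test of agreement between states, the alternatives for it and for width, and the counts of splits by peak presence were added later. By that rule the regions that can be named are the 10 in each direction whose lowest within-list score percentile, over the libraries that hold them, is highest. The text gives some of the leading ones and some of those past the threshold. Alternatives were stricter scores, lists of equal length, other rules for overlap and merging, 1000 bp bins, other pseudocounts and filters, quantile normalization, a replicate block and leaving out each library. A gene annotation of build mm9 was not used here, so 18 gene lists, promoter windows and distances to genes that had been planned were not analysed here, and no region is tied to a gene.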

Results

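Acetylation of histone H3 at lysine 27 (H3K27ac), a mark of active promoters and enhancers, was mapped by chromatin immunoprecipitation and sequencing in 266-6 cells, a mouse pancreatic acinar line. The cells received a non-targeting siRNA or siRNA against Arid1a, a DNA-binding subunit of the SWI/SNF chromatin remodelling complex, and then EGF, a ligand of the EGF receptor, or vehicle. Knockdown and intact here name the siRNA given, since the level of Arid1a was not analysed here and the labels do not say whether the siRNAs match the mouse gene. This gave 4 groups of 2 libraries, called control, EGF, Arid1a knockdown, and knockdown with EGF. Each library came as its own list of peaks with positions in build mm9. Read depth is unknown for all 8 libraries, so no counting interval is given for any value. Nothing in the labels says that the duplicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

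EGF-treated libraries held fewer peaks and less covered sequence than vehicle libraries, but the differences lay within what the replicates allow. The control libraries held 22167 and 28281 peaks, the EGF libraries 22361 and 23080, the knockdown libraries 26844 and 27558, and the knockdown libraries with EGF 22030 and 23256. Over both Arid1a states the mean was 22682 ± 582 peaks with EGF and 26213 ± 2760 without (SD, n = 4 each; two-sided exact permutation p = 0.114). Peaks covered 35.1 ± 1.32 Mb with EGF and 44.1 ± 6.61 Mb without (SD, n = 4; exact permutation p = 0.0857). The number of peaks of at least 10000 bp was 80.75 ± 13.1 with EGF against 147.75 ± 56.4 without (SD, n = 4; exact permutation p = 0.0857). The smallest p that 4 libraries against 4 allow is 0.0286, and the first control library, with as few peaks as an EGF library, decided the outcome: without it the exact permutation p was 0.0286 for both peak number and covered length.

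**Figure D1:**
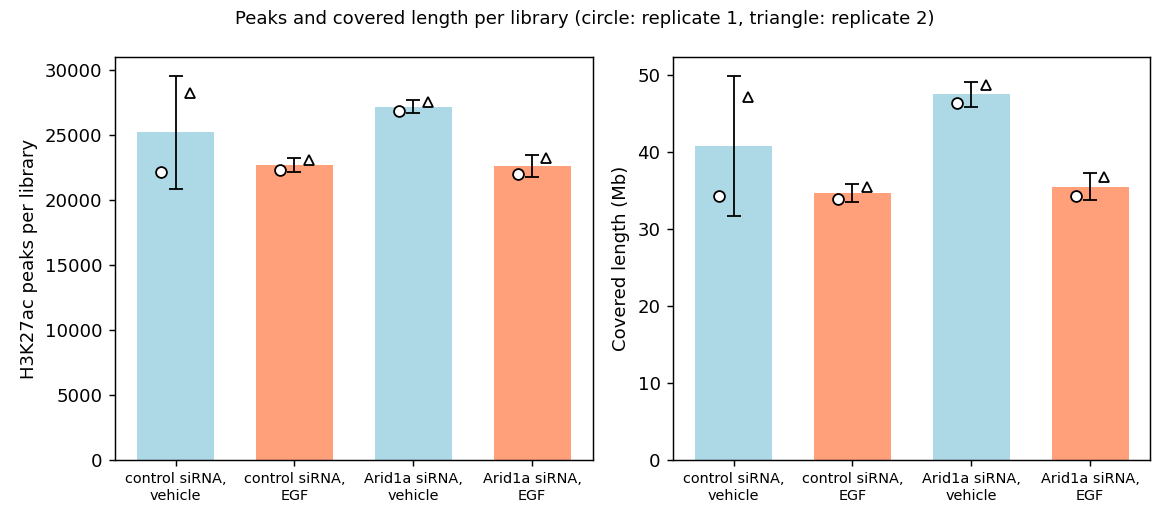
H3K27ac peaks per library (left) and sequence under peaks in Mb (right), by group. Bars are means, error bars are SD (n = 2), circles are replicate 1 and triangles replicate 2. The 2 control libraries lie apart at 22167 and 28281 peaks, and the 4 EGF-treated libraries lie between 22030 and 23256.

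Knockdown of Arid1a was not accompanied by a detectable change in these totals. Over both EGF states there were 24922 ± 2695 peaks with knockdown and 23972 ± 2899 with Arid1a intact (SD, n = 4; exact permutation p = 0.771). Covered length was 41.5 ± 7.06 Mb against 37.7 ± 6.34 Mb (SD, n = 4; exact permutation p = 0.343). Both tests leave the EGF difference in the spread, so they weigh knockdown only weakly. Without EGF, covered length was 47.5 ± 1.66 Mb with knockdown and 40.8 ± 9.09 Mb in control cells (SD, n = 2 each). With EGF it was 35.5 ± 1.81 Mb and 34.7 ± 1.14 Mb (SD, n = 2 each).

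Peak positions, unlike totals, grouped by EGF treatment. The peaks of all libraries merged to 33920 regions, of which 16607 (49.0%) had a peak in all 8 libraries, and these made up 73.8% of the merged length. A further 5774 regions had a peak in 1 library alone. Base-pair Jaccard indices (shared over total covered sequence) averaged 0.730 for the 4 same-group pairs and 0.655 for the 24 other pairs, the highest mean of all ways to pair the 8 libraries (one-sided exact permutation p = 0.00952). Parting the libraries by EGF gave a mean index of 0.709 within and 0.633 between the sides. That difference of 0.0761 was the highest of the 35 splits into 4 and 4, ahead of 0.0451 for the next (one-sided exact permutation p = 0.0286, the smallest possible). It was 0.0632 and 0.0662 without the first and second EGF library, and 0.0687 and 0.0725 without the first and second EGF-treated knockdown library, each with a one-sided exact permutation p of 0.0571. Parting them by Arid1a state gave a difference of 0.0105 (one-sided exact permutation p = 0.171). Every split above it was that by EGF or put the first control library with EGF-treated libraries alone. This test therefore does not weigh knockdown apart from EGF. The control pair was the least alike of the same-group pairs at 0.658, and the second control library was closer to the knockdown libraries, at 0.711 and 0.714, than to the first.

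**Figure D2:**
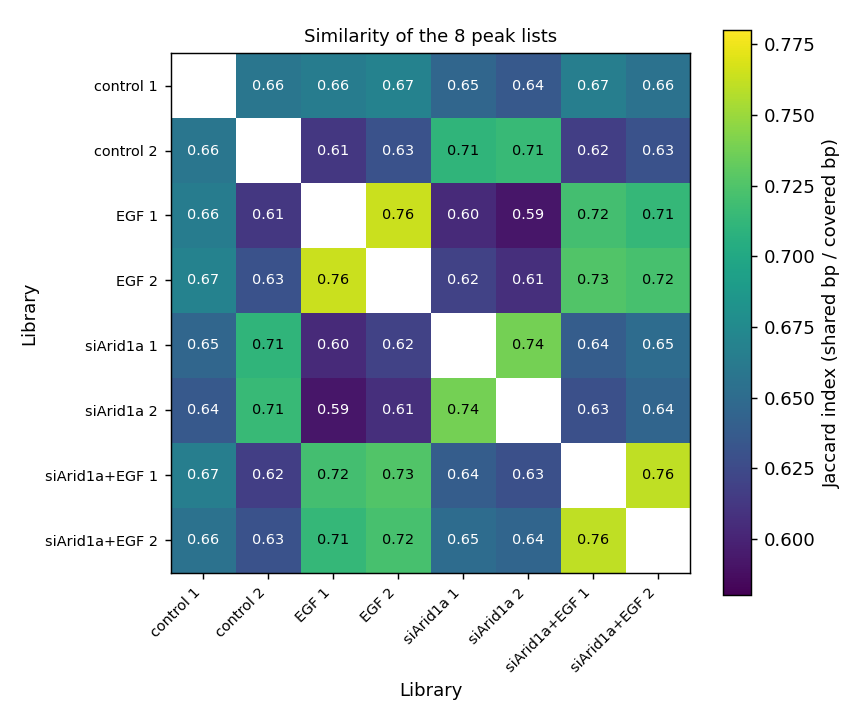
Base-pair Jaccard index for every pair of the 8 libraries, with colour and printed value giving the index from 0.59 to 0.76. The 4 EGF-treated libraries form a block above 0.71 whatever their Arid1a state, and the 2 control libraries share 0.66.

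The first comparison asks which regions EGF changed while Arid1a was intact. EGF-treated cells gained 678 regions, with a peak in both EGF libraries and neither control library, and lost 1444, with the reverse pattern. The gained region ranked first by peak score, on chromosome 15 from 64729153 to 64731019, was covered over 1773.5 ± 95.5 bp with EGF (SD, n = 2) and had no peak in either control library. By limma it rose by 3.30 ± 0.29 (SE, adjusted p = 0.0214) on the scale of log2(covered bp + 200). On chromosome 11, a region from 101645191 to 101646591 was covered over 1386 ± 21.2 bp with EGF and rose by 2.99 ± 0.29 (SE, limma adjusted p = 0.0214). Regions on chromosome 10 from 9222456 to 9224593, chromosome 5 from 64829220 to 64830982 and chromosome 6 from 50634355 to 50635779 rose by 3.45, 3.18 and 2.97 at the same adjusted p. Of the 10 gained regions ranked highest by score, 8 passed the limma test. Gained and lost regions were picked by peak presence in the libraries that limma tests again. Such tallies, here and below, are therefore no separate support. Of the 10 highest-ranked lost regions 3 passed, among them one on chromosome 15 from 88077561 to 88079307, which fell by 2.68 ± 0.40 (SE, limma adjusted p = 0.0300) from 1121.5 ± 473 bp in control cells (SD, n = 2), and one on chromosome 8 from 46417849 to 46419163, which fell by 2.35 ± 0.43 (SE, limma adjusted p = 0.0444).

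Over all 28146 regions with a peak in at least 2 libraries, limma called 296 higher and 815 lower with EGF. The other ways to split the same 4 libraries in pairs changed 713 and 456 regions, against 2122 for the real one. Lists of equal length gave 1159 gained and 1060 lost, and limma after quantile normalization 603 higher and 580 lower, but both settings push the directions towards balance whatever the cause. Limma on lists of equal length, whose peak widths are not evened, called 660 higher and 888 lower. The excess of losses rested on the second control library: without it 2050 regions were gained and 1822 lost, and without the first 744 and 5927, while leaving out the first or second EGF library gave 1354 and 1942, or 1110 and 2219. Here and below, leaving out a library can only raise such counts. Fewer libraries of its group must then hold a peak. This favours losses without a control library and gains without an EGF library. Limma called 897 higher and 518 lower without the second control library and 2110 in all without the first, 464 and 482 without the first and second EGF-treated knockdown library, 1 without the second EGF library, and 0 without the first EGF library or either vehicle knockdown library (3741 to 4818 at an unadjusted p under 0.05).

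In knockdown cells EGF was set against vehicle in the same way, and losses again outnumbered gains, with 338 regions gained and 2850 lost. The region gained with the highest rank lay on chromosome 10 from 79951426 to 79953448, covered over 1778.5 ± 346 bp with EGF (SD, n = 2) and without a peak in either vehicle library, a rise of 3.30 ± 0.64 (SE, limma adjusted p = 0.0396). A 4240 bp region on chromosome 13 from 58043266 to 58047505 rose by 4.38 ± 0.80 (SE, limma adjusted p = 0.0339), and one on chromosome 18 from 38760365 to 38762041 by 2.98 ± 0.30 (SE, limma adjusted p = 0.0154). The regions on chromosomes 11 and 15 that led the gains in Arid1a-intact cells were gained here as well, by 2.97 ± 0.29 for the first (SE) and at a limma adjusted p of 0.0154 for both. Among lost regions, one on chromosome 8 from 8488213 to 8489549 fell by 2.35 ± 0.36 (SE, limma adjusted p = 0.0221) from 833.5 ± 216 bp, and one on chromosome 2 from 24909615 to 24911147 fell by 2.97 ± 0.55 (SE, limma adjusted p = 0.0351) from 1371.5 ± 210 bp (SD, n = 2). Of the 10 highest-ranked regions in each direction, 7 gained and 7 lost passed.

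Limma called 175 regions higher and 1689 lower with EGF in knockdown cells. The other splits of these 4 libraries changed 392 and 355 regions, against 3188. On lists of equal length the counts were 843 gained and 1050 lost, with 471 higher and 1188 lower by limma. Limma after quantile normalization left 380 higher and 522 lower. Leaving out one knockdown library gave 529 gained and 5336 lost, or 691 and 4844, and leaving out one library of the EGF-treated knockdown cells 1004 and 3530, or 626 and 4101. The rule favours losses in the first case. In the second it favours gains, and losses still outnumbered them. By limma, 0 regions were called without the first or the second knockdown library or without the first EGF-treated one (4882, 4540 and 4878 at an unadjusted p under 0.05), and 62 without the second EGF-treated one, against 3908 and 4050 without the first and second control library and 894 and 865 without the first and second EGF library.

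**Figure D3:**
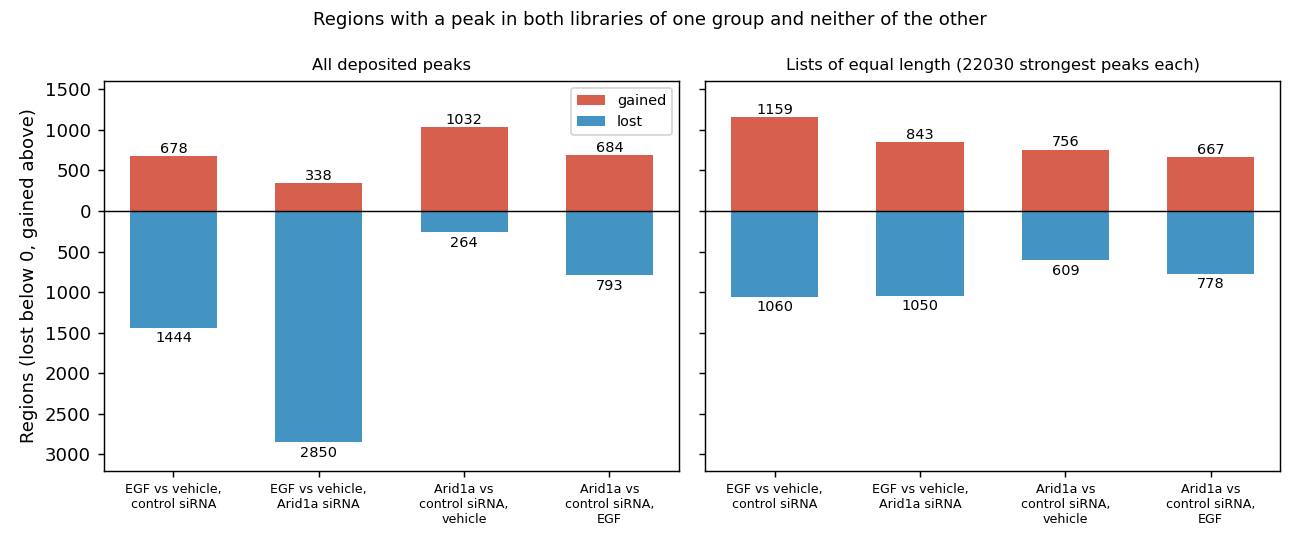
Number of regions gained (above 0) and lost (below 0) in the 4 pairwise comparisons, for all deposited peaks (left) and for the 22030 highest-scoring peaks of each list (right). EGF losses of 1444 and 2850 regions on the left stand against 1060 and 1050 on the right.

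Many regions changed with EGF in both Arid1a states. Over all 8 libraries 137 regions were gained and 545 lost, with a peak in all 4 libraries of one treatment and none of the other. A further 14 regions changed in opposite directions, so that 98.0% of those changed in both states went the same way (Fisher's exact test, p = 7.77e-129, over regions, which are not independent replicates). Among 9664 regions with a peak in 2 to 6 libraries, independent lists of these sizes would share 23.7 gained and 426 lost, against 137 and 545 seen. Independent lists would thus already share most of the number of losses, though few of the gains. The region on chromosome 11 from 101645191 to 101646591 ranked first, covered over 1386 ± 21.2 bp in EGF cells and 1371.5 ± 27.6 bp in EGF-treated knockdown cells (SD, n = 2 each) with no peak in any vehicle library. It rose by 2.98 ± 0.21 over both states (SE, limma adjusted p = 0.00503). The regions starting at 64729153 on chromosome 15, 38760365 on chromosome 18 and 9222456 on chromosome 10 rose by 3.15, 3.08 and 3.33 at the same adjusted p. Of lost regions, one on chromosome 6 from 135508959 to 135510774 fell by 3.17 ± 0.22 (SE, limma adjusted p = 0.00503), from 1589.5 ± 320 bp in control and 1622.5 ± 51.6 bp in knockdown cells (SD, n = 2 each). A region on chromosome 17 from 27844752 to 27845570 fell by 2.20 ± 0.22 (SE, limma adjusted p = 0.00609). All 10 of the highest-ranked regions in each direction passed, which their choice by peak presence in the same libraries favours. On chromosome 19, a stretch of 44.5 kb from 53478108 to 53522572, chosen after the values were seen, held 3 regions gained in both states beside 1 with a peak in all 8 libraries.

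**Figure D4:**
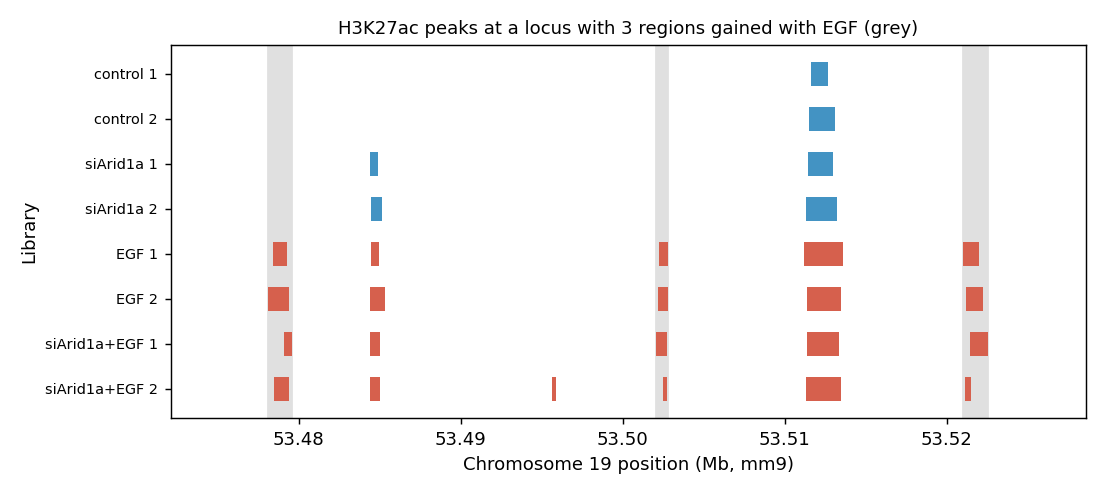
H3K27ac peaks in the 8 libraries (rows) along chromosome 19 from 53478108 to 53522572, with position in Mb of build mm9, vehicle libraries in blue and EGF-treated libraries in red. The 3 grey regions have a peak in all 4 EGF-treated libraries and in no vehicle library.

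Limma's mean EGF effect over both states gave 503 regions higher and 3151 lower, with a median log2 difference of -0.25 over all regions. Quantile normalization, which moved that median to 0.04, gave 1592 higher and 1468 lower. On lists of equal length limma still called 957 higher and 2524 lower. By peak presence the same lists gave 307 gained and 245 lost in all 8 libraries. Without the first control library 140 regions were gained and 1432 lost, and limma called 5974 in all, against 1279 without the second knockdown library, 1474 and 1920 without the first and second EGF library, 1557 without the first knockdown library, and 1596 and 2098 without the first and second EGF-treated knockdown library.

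The next comparison asks which regions differed with Arid1a knockdown in the absence of EGF. Knockdown cells gained 1032 regions and lost 264 against control cells. The 10 gained regions ranked highest were 257 to 1077 bp wide. The first, on chromosome 14 from 47441510 to 47441842, was covered over 309.5 ± 33.2 bp (SD, n = 2), and 0 of these 10 passed the limma test (smallest adjusted p = 0.0896; limma called 3576 of all regions at an unadjusted p under 0.05). Of the 10 highest-ranked lost regions, 2 passed. One on chromosome 17 from 15367822 to 15369140 fell by 2.64 ± 0.35 (SE, limma adjusted p = 0.0390) from 1070.5 ± 351 bp, and one on chromosome 10 from 53821650 to 53822816 by 2.25 ± 0.29 (SE, limma adjusted p = 0.0386) from 755 ± 106 bp (SD, n = 2). The first also had no peak in EGF-treated knockdown cells and 763.5 ± 31.8 bp in EGF cells.

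Limma called 308 regions higher and 77 lower with knockdown, and another split of the same 4 libraries changed 1013 regions against 1296 for the real one. Lists of equal length gave 756 gained and 609 lost, and quantile normalization 0 limma calls (3114 at an unadjusted p under 0.05). The direction depended on the control library kept: without the first 1186 regions were gained and 2659 lost, and without the second 3924 and 454. Without the first or second knockdown library the counts were 2910 and 510, or 2454 and 652. With 1 control library left, a loss needs a peak in 1 library and a gain in 2, which favours losses. The median log2 difference by limma was 0.01 without the first control library and 0.34 without the second, so it showed no turn to losses. Limma made 2956 calls without the second control library and 0 without any other single library (2429 to 3296 at an unadjusted p under 0.05).

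In EGF-treated cells knockdown went with 684 regions gained and 793 lost, a majority that depended on the setting. A 2196 bp region on chromosome 9 from 70806619 to 70808814 was covered over 1871 ± 140 bp in EGF cells (SD, n = 2), had no peak in EGF-treated knockdown cells, and fell by 3.37 ± 0.20 (SE, limma adjusted p = 0.0307). It kept 1192.5 ± 185 bp in knockdown cells without EGF. A region on chromosome 13 from 49273954 to 49274885 had 780 ± 215 bp in EGF cells (SD, n = 2), no peak in any library of the other groups, and fell by 2.28 ± 0.31 (SE, limma adjusted p = 0.0471). Among the 10 highest-ranked gained regions the one nearest to the threshold, on chromosome 16 from 90934211 to 90935627, had 977.5 ± 17.7 bp with knockdown and none in EGF cells (log2 difference 2.56 ± 0.38 SE, limma adjusted p = 0.0577). Of the 10 highest-ranked regions in each direction, 0 gained and 2 lost passed.

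Limma called 66 regions higher and 120 lower, and the other splits of these 4 libraries changed 444 and 389 regions against 1477. Lists of equal length gave 667 gained and 778 lost. Peaks above the pooled median score turned the majority, with 698 gained and 197 lost and limma calling 396 higher and 124 lower, as did 1000 bp bins (1702 gained, 1453 lost) and a required cover of 50% of the region (1019 gained, 966 lost). Without the first EGF-treated knockdown library the majority turned, with 1845 gained and 1138 lost, while the other left-out libraries gave 1094 and 1795, 1346 and 1436, or 1241 and 1529. Limma calls fell to 0 without either EGF library, either vehicle knockdown library or the first EGF-treated knockdown library, and to 4 without the second (2432 to 2788 at an unadjusted p under 0.05), and rose to 495 and 630 without the first and second control library.

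Over both EGF states 88 regions were gained with knockdown and 44 lost in all 8 libraries. The highest-ranked lost region, on chromosome 1 from 71419603 to 71422834, was covered over 2727.5 ± 713 bp in control and 1320 ± 878 bp in EGF cells (SD, n = 2 each), had no peak in any knockdown library and fell by 3.32 ± 0.34 (SE, limma adjusted p = 0.0421). Another on the same chromosome, from 73096935 to 73098410, fell by 2.74 ± 0.25 at the same adjusted p. On chromosome 4, a region from 116874336 to 116875717 had 1187 ± 65.1 bp and 658 ± 239 bp in the knockdown groups without and with EGF (SD, n = 2 each) and rose by 2.43 ± 0.25 (SE, limma adjusted p = 0.0421). On chromosome 11, one from 74451637 to 74452436 rose by 1.84 ± 0.22 (SE, limma adjusted p = 0.0483). Of the 10 highest-ranked regions in each direction, 2 gained and 5 lost passed. The same 14 regions that went opposite ways with EGF also did so with knockdown, since both describe one pattern over the 4 groups. Of the regions changed in both EGF states, 90.4% went the same way (Fisher's exact test over regions, p = 2.10e-24). Independent lists of these sizes would share 73.0 gained and 21.7 lost, near the 88 seen for gains.

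Limma's mean knockdown effect gave 60 regions higher and 39 lower. In the simulation with reshuffled residuals, unchanged regions reached the same p limit at numbers equal to 54.5% of these calls. For knockdown without and with EGF it was 32.5% and 43.0%, so knockdown regions past the threshold may include many false calls. Quantile normalization turned the majority, with 158 of the calls lower, and so did leaving out the first control library, with 103 regions gained and 127 lost and limma calling 81 higher and 113 lower. Without the second control library 287 were gained and 47 lost and limma made 2772 calls. The all-library count was 204, 229 and 202 without the first knockdown library and without the first and second EGF-treated knockdown library, and leaving out any EGF-treated or knockdown library ended the limma calls (3591 to 4330 at an unadjusted p under 0.05).

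Whether the EGF effect depended on Arid1a was tested as the difference of both EGF effects. Limma called 0 of 28146 regions (2525 at an unadjusted p under 0.05, smallest adjusted p = 0.153). Of the 678 regions gained with EGF in Arid1a-intact cells, 313 (46.2%) had a peak in both EGF-treated knockdown libraries and 180 in neither, and 124 already had one in both vehicle knockdown libraries. Of the 1444 regions lost, 1047 (72.5%) had a peak in both vehicle knockdown libraries and 894 (61.9%) in neither EGF-treated one. The count of 0 did not hold for peaks above the pooled median score, where limma called 273 regions higher and 539 lower, nor without the second control library, with 36 higher and 1098 lower.

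Changed regions were narrower than shared ones, as are regions with a peak in few libraries in general: median width was 737 bp with a peak in 2 libraries, 1318 bp in 6 and 2210 bp in all 8. The widths below therefore tell nothing of change itself. Regions gained with EGF in Arid1a-intact cells had a median width of 972 bp and 3.98% were at least 2000 bp wide, against 2154 bp and 55.5% for the 17693 regions with a peak in all 4 libraries. Lost regions had a median of 1177.5 bp, with 14.6% that wide. The share of wide regions ranged from 2.27% to 16.1% over the gained and lost sets of all comparisons. Peaks in these gained and lost regions had a median within-list score percentile of 12.9 and 13.4, against 55.9 and 58.1 for shared regions. Most were thus weak, and a small shift across the caller's limit can make such a peak appear or vanish. Only 27 of the 2122 regions had peaks above the pooled median score on one side and none at any score on the other. For EGF over both states it was 4 of 682. Of 240 tests of a chromosome's share, 1 passed: 10 of 1444 EGF-lost regions (0.693%) lay on the X chromosome, against 2.05% of shared regions (Fisher's exact test, Benjamini-Hochberg adjusted p = 0.0226). A low share on X was not particular to EGF losses. It lay below that of shared regions in every changed set but the regions gained with knockdown over both EGF states (3.41% against 2.13%).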

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

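Of the tests in this part, those that count how many regrouped libraries change as many regions by peak presence, for EGF and for knockdown, were chosen after the result was seen. The 14 regions with opposite EGF effects in the 2 Arid1a states were singled out because each had a peak in all libraries of one treatment and none of the other, in reverse directions in the 2 states. Of these, 13 had a peak with EGF alone and with knockdown alone but not with both or with neither, and 1, on chromosome 16 from 84392061 to 84392658, had the reverse. The limma test of the difference of EGF effects, which covered these regions, called none of them (smallest adjusted p over all regions 0.153). Opposite patterns as frequent arose in 23 of the 35 ways to part the libraries, with a median of 20, so their number does not stand apart.

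A first pattern is the change in peak positions with EGF, 137 regions gained and 545 lost over all 8 libraries. The number of peaks per list alone does not account for the split: with lists cut to one length 552 regions still separated the treatments, against 182 for the highest other split. Depth or yield unrelated to EGF stay open, since cutting lists evens the number of peaks but not their width. On such lists limma's mean EGF effect still had a median log2 difference of -0.17 and gave 957 regions higher and 2524 lower. By peak presence 1 of 35 splits, the real one, gave as many as 682 regions (highest other 194). By a 2-group limma fit 1 of 35 gave 2206 (highest other 63). Both are the smallest share that 35 splits allow. They speak against chance only if all 8 libraries are independent, which the labels do not say. The excess of losses stays open. By peak presence, lists of one length, on which 44.4% of changed regions were lost (43.0% to 51.3% without single libraries), balance gains and losses whatever the cause. An effect of EGF on H3K27ac may remain as a hypothesis for the split.

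A second pattern is the control pair. The second control library was closer to the vehicle knockdown libraries than to the first control library, by 0.0544 in mean index. A larger number of peaks is not the whole cause. On lists of equal length the gap fell to 0.0286 (0.0277 and 0.0294 for the 2 knockdown libraries), so that number may account for the part that was lost. Cutting lists does not even peak width, so depth or yield stays open here too. In the full lists median width was 1270 bp in the second control library and 1207 bp in the first. It was 1302 and 1312 bp in the vehicle knockdown libraries. That this library came from knockdown cells is opposed by regions that part knockdown from intact cells under EGF: 69.4% of those gained and 76.0% of those lost with knockdown had a peak in it, a difference of -6.60 percentage points, near the -8.04 of the first control library and far from 29.0 and 31.6 in the knockdown libraries. The surplus of knockdown gains without EGF may stem from the short list of the first control library. This cannot be told apart from an effect of knockdown. Without that library the gained share fell from 79.6% to 30.8%, past the 46.3% seen with EGF, and the outcome rests on which control library is kept. With 1 control library a loss needs a peak in 1 library and a gain in 2, so 30.8% and 46.3% come from unlike rules. For knockdown effects over both EGF states counts of splits cannot decide on chance: 3 of 35 splits changed at least 132 regions (highest other 682, the split by EGF). On lists of equal length 2 of 35 changed at least 182 (highest other 552), and with 11015 peaks per list 2 of 35 at least 110 (highest other 339), the second being the split by EGF each time. Such counts take in splits that carry the EGF pattern, so they do not weigh knockdown apart from EGF. Regions that part knockdown from intact cells in one EGF state can be read in the libraries of the other. Those set without EGF gave differences of -19.4 and -22.2 percentage points in the EGF libraries. In the EGF-treated knockdown libraries they gave 19.9 and 22.4, and signs held on lists of equal length. Since 2 libraries against 2 cannot give a two-sided p under 0.333, chance stays undecided. By the 2-group limma fit, which leaves EGF in the spread and so calls fewer regions than the fit with 4 group means, 4 of 35 gave as many calls as the real 1 (highest other 2206, again the split by EGF).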

How the results depend on the processing

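The checks of width and of the agreement between states were added after seeing the data. All kept their direction and call, though that of width is set by how regions are defined, as did the similarity of replicates and the knockdown effects on peak sets and totals, under every setting tried. Peak number and covered length with EGF passed only without the first control library. With a replicate block the EGF difference of 0.0761 had a one-sided exact permutation p of 0.0556, the smallest its 18 splits allow. Gene-based alternatives were not run. Counts follow in the order EGF in intact cells, knockdown without EGF, EGF in knockdown cells and knockdown with EGF, then EGF and knockdown over both states, and only those that moved by over 1.5 times or turned their majority are given. Unless stated, the cause was not tested.

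Regions gained and lost numbered 4828, 3571, 7288, 3155, 1384 and 255 in 1000 bp bins, which divide wide regions, with a turned majority for knockdown with EGF (1702 gained, 1453 lost). Where a peak had to cover at least 50% of the region, knockdown without EGF gave 2055 and knockdown with EGF 1985, its majority turned (1019 gained, 966 lost). Only peaks above the pooled median score gave 1101, 855, 1799, 895 (turned, 698 gained and 197 lost) and 358 for EGF over both states. On lists of equal length EGF gave 2219 in intact cells (turned, 1159 gained and 1060 lost), 1893 in knockdown cells and 552 over both states (turned, 307 and 245). With 11015 peaks per list the counts were 1333 (turned, 687 and 646), 742, 1082, 893 (turned, 453 and 440) and 339 (turned, 185 and 154). Presence above the pooled median score with absence at any score left 27, 8, 34, 9 (turned, 8 and 1), 4 and 0.

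Limma calls changed with quantile normalization to 1183 (turned, 603 higher and 580 lower), 0, 902, and over both states 3060 for EGF (turned, 1592 and 1468) and 263 for knockdown (turned, 158 lower). On lists of equal length they were 641 and 519 for knockdown without and with EGF and 887 over both states. With a pseudocount of 50 bp these were 842, 508 and 844, and with 1000 bp 121, 0 and 3. Without a filter they were 0, 98 and 0, with 706 for EGF in intact cells, and with peaks in at least 4 libraries 0 without EGF and 194 over both states. Peaks above the pooled median score gave 678, 1114 for EGF in knockdown cells, 520 (turned, 396 and 124), 812 for the difference of EGF effects, 1793 for EGF over both states and 1109 for knockdown over both states.

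The replicate numbers did not pair the libraries (correlations of deviations -0.00929 to 0.0317), and the block moved limma calls to 0, 0, 1176, 0 and, for knockdown over both states, 0, while EGF over both states kept 2958.

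Leaving out one library in turn, which leaves a lone library that is assumed to vary like the others, gave these ranges. The EGF difference was -4879 to -2841 peaks and -12.3 to -7.50 Mb, and its effect on peak sets 0.0632 to 0.107, past the threshold without any vehicle library but not without any EGF-treated one (one-sided exact permutation p = 0.0571). The knockdown difference kept its sign but varied widely, from 71.1 to 2386 peaks and 1.40 to 6.94 Mb, and its effect on peak sets from 0.00296 to 0.0255. Regions gained and lost ranged from 3296 to 6671, 3106 to 4378, 4534 to 5865 and 2770 to 2983, and over both states from 801 to 1572 and 185 to 334. With a library left out fewer libraries must meet the rule, so these counts can only rise and do not show how stable the full counts are. Limma calls ranged from 0 to 2110, 0 to 2956, 0 to 4050, 0 to 630, 1279 to 5974 for EGF and 0 to 2772 for knockdown over both states, and 0 to 1134 for the difference of EGF effects. The majority turned without the second control library for EGF in intact cells (3872 regions, 1415 limma calls), without the first for knockdown without EGF (3845) and over both states (230 regions, 194 calls), and without the first EGF-treated knockdown library for knockdown with EGF (2983). Read depth is unknown, so no result can be weighed against it.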

Other observations

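Of the tests in this part, the agreement of effects between states was added after the data were seen. Regions gained with EGF in both Arid1a states lay near another such region more often than random draws did, though most did not. Of the 137, 12.4% lay within 50 kb of another, against 1.47% ± 1.46 (SD) in 10000 random draws of as many regions from those with a peak in 2 to 6 libraries (one-sided permutation p = 0.0001, the smallest possible). Of the 545 lost, 8.26% did, against 5.72% ± 1.39 (one-sided permutation p = 0.0425). Grouping was not particular to EGF. Of regions gained with knockdown under EGF 15.6% lay near another against 7.11% at random (one-sided permutation p = 0.0001). Without EGF it was 14.9% of those gained against 10.5% and 7.58% of those lost against 2.81% (one-sided permutation p = 0.0009 and 0.0032). Over both EGF states 2.27% of knockdown gains did against 0.999% (one-sided permutation p = 0.359). At one locus, on chromosome 19 from 53478108 to 53522572 (44.5 kb), 3 of 6 regions had a peak in all 4 EGF-treated libraries and in no vehicle library. Similar groups of 3 lay on chromosome 3 from 54869544 to 54894027 and on chromosome 6 from 142475948 to 142516950. These loci were chosen for their density after their values were seen.

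A candidate explanation is that whole loci respond to EGF, for which the lower of both p-values, doubled, was 0.0002, but the grouping of knockdown sets leaves open a cause that is not specific to EGF. A domain broken into peaks at most 5 kb apart is opposed for gained regions. With peaks within 5 kb merged beforehand 9.90% still lay within 50 kb of another against 0.747% at random (one-sided permutation p = 0.0002). Pieces of a domain that lie further apart would not have been merged, so a broader domain stays open. For lost regions merging left 4.44% of 405 near another against 2.999% ± 1.193 (SD) at random (one-sided permutation p = 0.151). The share fell about as much as that of random draws and fewer regions were left, so grouping of lost regions stays undecided. What genes lie at these loci was not analysed here.

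Limma differences between treatments, taken in the 2 Arid1a states from separate libraries, correlated across regions for EGF (Pearson's r = 0.552, Spearman's rho = 0.533, 28146 regions, which are not independent replicates) and less for knockdown in the 2 EGF states (Pearson's r = 0.307, Spearman's rho = 0.306). Of 531 regions that limma called for EGF in both states, 529 went the same way, 91 higher and 438 lower, against 1.84 and 48.9 for independent lists. For either factor both lists of calls rest on a single estimate of spread per region. Some excess over independent lists can therefore arise without a shared effect. For knockdown 12 regions were called in both EGF states and 11 went the same way. Independent lists would share 0.722 higher and 0.328 lower, against 8 and 3. On lists of equal length 90 were called in both and 83 went the same way, against 4.04 higher and 2.51 lower for independent lists. Of regions called for knockdown without EGF, 34.3% of 385 had the same sign with EGF, and 57.1% of 641 on lists of equal length. For EGF, 84.3% of 1111 regions called in intact cells had the same sign in knockdown cells, and 74.7% of 1548 on lists of equal length. Signs were taken from unrounded differences. For knockdown the median difference with EGF was 0 over the regions called higher and -1.78e-15 over those called lower. A value that small is rounding error but still carries a sign, so the knockdown shares are not exact.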
